A study of Mus musculus with 24 samples.

How the data were processed

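RNA from whole brain and liver of C57BL/6J male mice was taken after 5 weeks on diets with 2.25, 0.4, 0.1 or 0 ppm selenium, with 3 libraries for each of 8 groups of tissue and diet, 24 in all. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with the TruSeq Stranded Total RNA kit. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.33, STAR 2.5.2b, RSEM 1.3.0, limma 3.34.5 and the mouse genome build mm10. Metabolite and microRNA profiles that the series also names were not analysed here.

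The deposited table held a normalized signal for 21894 genes in each of the 24 libraries, which the authors had made by dividing each library's reads by a single factor, as the values themselves show. When multiplied by that factor, 525456 of 525456 values (100%) lay within 0.01 of a whole number of reads, and the factors matched median-of-ratios size factors over all 24 libraries. The factor puts brain and liver on a shared scale, and its choice can move the balance of higher and lower genes, so the main splits were recomputed under other scalings. Depth on genes was 11.5 to 18.4 M reads in liver and 12.9 to 17.8 M in brain, and a count of 3 reads corresponded to 3.12 to 5.32 normalized reads in liver and 1.75 to 2.34 in brain, for counting error only. The symbols of 16 genes occurred more than once. Genes with near-identical copies, such as the major urinary proteins, Serpina1e, Hspa1a, Hspa1b, Ifit3, Ifit3b and members of the Cyp2 and Cyp3 families, are uncertain because reads can be split between copies.

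The columns name a tissue and a diet but no replicate number, so libraries within a group were called a, b and c in column order, a name that pairs nothing, and nothing links the brain and liver columns of an animal. The p-values measure the spread between these libraries, which may be technical. Over genes with at least 20 reads, the 24 pairs of libraries within groups differed by a chi-square of 4.01 to 56.5 per gene, above sampling noise, and each library was counted as a replicate.

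Differences between diets were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with moderated variances that follow the mean, on genes at 1 or more in at least 3 libraries of the tissue. The 4 diets of a tissue entered a single fit, so the 12 libraries share the estimate of spread. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Contrasts were 0 ppm against the mean of the 3 supplemented diets, 0 against 0.1 ppm, 0.4 against 0.1 ppm, 2.25 against 0.1 ppm, any difference among diets, and the 0 ppm contrast in liver minus the same in brain over all 24 libraries. Fold changes are on the log2(value + 1) scale and understate changes of low genes.

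Lists of genes were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the lists with at least 3 measured members. Of 53 lists, 50 were fixed beforehand, 22 of them markers of cell types and brain regions, and 3 were lists of NRF2-dependent genes that the study deposited. The latter held 147, 18 and 60 symbols, of which 130, 16 and 55 matched the table and 12, 2 and 21 were shared with the fixed NRF2 list. The tests, lists, comparisons and the rule for named genes were chosen before the data were examined. That rule took up to 12 genes with the largest change each way among those past the threshold whose libraries did not overlap, or the 5 smallest p where fewer than 5 passed. It added every selenoprotein past the threshold or else the 3 with the smallest p, up to 4 members of each list that passed, and Gpx1, Selenow, Selenop, Gpx4 and Txnrd1. Predicted and unnamed loci were counted but not named, and a few genes that the rule took are not reported here.

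Alternatives planned with the tests were no filter on low values, a filter at 4, a pseudocount of 0.1, quantile normalization, robust moderation, no mean-variance trend, a threshold of 0.1, a fit on only the 6 libraries compared, an estimated correlation in camera, and leaving out each library in turn. Chosen after seeing the data were the quasi-likelihood test of edgeR 4.0.16 with TMM scaling on the recovered reads, 2 principal components of the clock genes as covariates, leaving out the 2 brain libraries richest in pituitary transcripts, and leaving out 827 genes at least 100 times higher in liver than in brain. The edgeR test called 1372 liver genes for the 0 ppm contrast, 1131 of them shared with limma.

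The procedure was tested on simulated data with 50 genes changed at each of 4 fold sizes. The changed genes were drawn only from those above a minimum mean, and all genes were simulated as independent. Recovery of low genes and false calls from structure shared by libraries were therefore not tested. For the 0 ppm contrast it recovered 54% of 1.5-fold and 82% of 2-fold changes in liver (18668 genes) and 84% and 96% in brain (21037 genes). For 2.25 against 0.1 ppm it recovered 50% and 88% in liver (18660 genes) and 62% and 90% in brain (21042 genes), and for the difference between tissues 54% and 80% (18186 genes). False calls made up 1.20% and 6.86% of calls in liver, 6% and 7.37% in brain and 7.47% for the difference. In the list test on brain (21127 genes, simulated as independent), a list of 30 genes shifted by 0.2 passed and 0 of 50 random lists did, by camera at the preset or the estimated correlation.

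The authors' deposited p-values were given for 12 comparisons, 6 per tissue. All 247176 of these p-values were within 1e-06 of an equal-variance test of 2 group means on the linear values, as checked by recomputation, and 24 repeated columns of library values beside them were not used. Coordinates come from GENCODE M21 on the same build, which matched 17753 of 21894 gene identifiers with their version and 21821 without. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.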

Results

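RNA was measured by sequencing in whole brain and liver of male C57BL/6J mice, an inbred laboratory strain, that ate diets with 2.25, 0.4, 0.1 or 0 ppm selenium for 5 weeks from 8 weeks of age. Selenium is a trace element that cells build into selenoproteins as the amino acid selenocysteine. Each tissue and diet had 3 libraries, 24 in all, called a, b and c within a group in the order of their columns. Liver libraries held 11.5 to 18.4 M reads on genes and brain libraries 12.9 to 17.8 M. Values are the authors' normalized read counts per gene, given as mean ± SD with n = 3, and changes are log2 differences with their standard error (SE) from limma. Genes named with values were picked, after their values were seen, from those a fixed rule selected, except where stated.

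The series title sets selenium deficiency beside longevity, and the first comparison asked which liver genes differed without dietary selenium. The transcripts of several selenoproteins were lower at 0 ppm than at the supplemented diets. Gpx1, the cytosolic glutathione peroxidase, fell from 26972 ± 1263 normalized reads at 0.1 ppm to 10497 ± 1028 at 0 ppm, 2.64-fold below the mean of the supplemented diets. Selenow, a small selenoprotein of the cytosol, fell from 1069 ± 33.6 to 342 ± 27.2, 3.32-fold below that mean. Selenoh, a nuclear selenoprotein, and Selenop, the liver-secreted selenium carrier of plasma, fell as well, Selenop from 140610 ± 13802 to 94827 ± 2602. Gpx4, which removes lipid peroxides, stood at 4006 ± 383 at 0 ppm and 3678 ± 91.5 at 0.1 ppm, and did not pass the test.

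Against the mean of the 3 supplemented diets, the liver log2 changes were -1.40 for Gpx1 (SE 0.07, adjusted p = 2.47e-07), -1.73 for Selenow (SE 0.07, adjusted p = 9.26e-09), -1.15 for Selenoh (SE 0.14, adjusted p = 0.000278) and -0.65 for Selenop (SE 0.11, adjusted p = 0.00266). Msrb1, a methionine sulfoxide reductase, changed by -0.30 (SE 0.05, adjusted p = 0.00428). Of the 22 selenoprotein genes measured in liver, 7 fell and 2 rose, and 10 were lower and 3 higher when adjusted over the list alone. The list passed camera downward (adjusted p = 0.000235; adjusted p = 0.142 with an estimated correlation). The other called members were Txnrd2, Selenoo, Selenoi and Sephs2, with changes between -0.35 and 0.30, and each lost its call in some fits without a single library. At 0, 0.1, 0.4 and 2.25 ppm Selenoi averaged 1588, 1098, 1277 and 1537 normalized reads and Selenoo 608, 936, 722 and 640. For both, the 2.25 ppm mean was the nearest to that at 0 ppm. Txnrd2 was lost without 0 ppm a, b or c, 0.1 ppm c, 0.4 ppm a or 2.25 ppm b (adjusted p = 0.0515 to 0.102), and Selenoi without 0 ppm a or b (0.103 to 0.156). Selenoo was lost without 0 ppm a or b, 0.1 ppm b or c, 0.4 ppm a or b, or 2.25 ppm a or b (0.0509 to 0.211), and Sephs2 without any 0 ppm library, 0.1 ppm c, 0.4 ppm a or b, or 2.25 ppm a or c (0.0508 to 0.133). Gpx4 changed by 0.10 (SE 0.06, adjusted p = 0.39) and Txnrd1, the cytosolic thioredoxin reductase, by -0.15 (SE 0.07, adjusted p = 0.223). Gpx1 (ENSMUSG00000063856.7) lies on mm10 chromosome 9 from 108338903 to 108340343 on the plus strand, Selenow (ENSMUSG00000041571.9) on chromosome 7 from 15917208 to 15922402 on the minus strand, and Selenop (ENSMUSG00000064373.11) on chromosome 15 from 3268547 to 3280508 on the plus strand. All genes with coordinates given are protein-coding, and a value covers the whole gene.

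**Figure D1:**
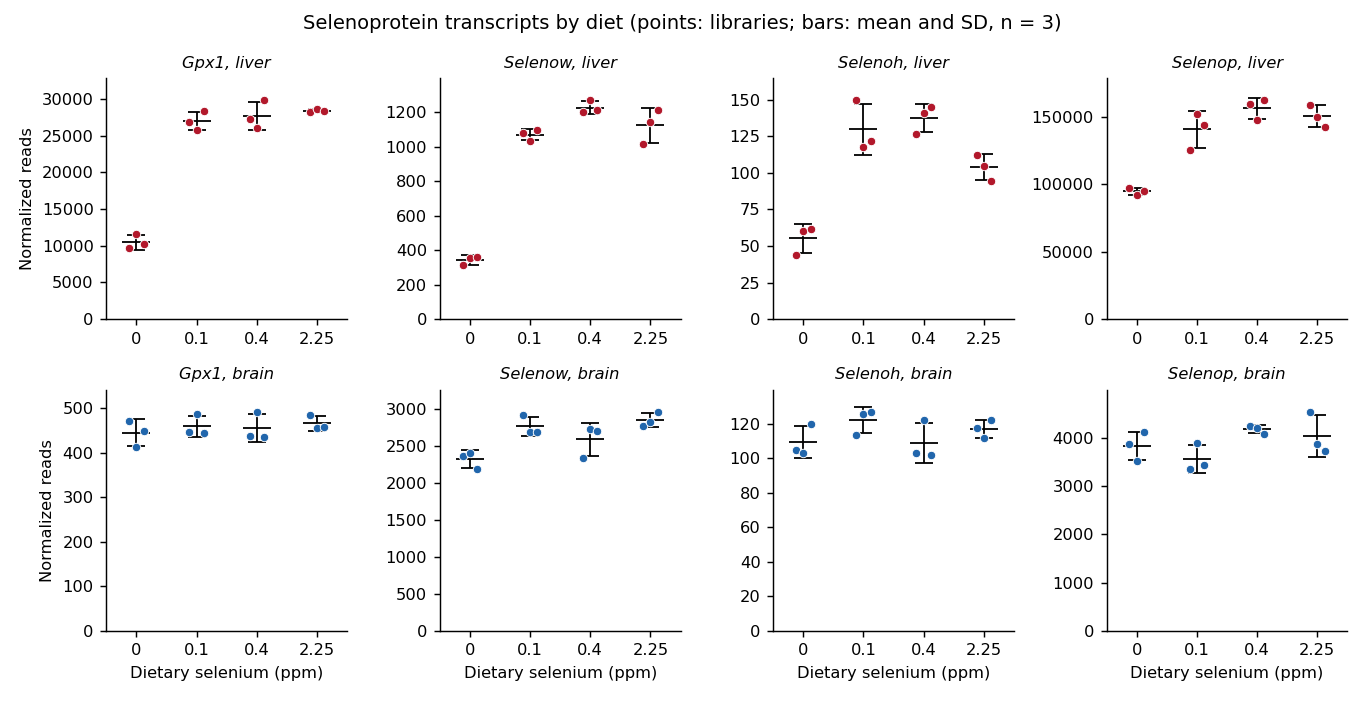
Normalized reads of Gpx1, Selenow, Selenoh and Selenop against dietary selenium (ppm), with each liver and brain library as a point and the mean and SD of 3 libraries as a bar. In liver the 0 ppm mean of Gpx1 is 10497 against 26972, 27693 and 28382 at 0.1, 0.4 and 2.25 ppm, while in brain the means lie between 445 and 466.

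Among the other liver genes at 0 ppm, Slc16a5, a monocarboxylate transporter, and Eif4ebp3, a translation repressor, were among the largest decreases. Their log2 changes were -2.66 (SE 0.25, adjusted p = 6.40e-05) and -2.62 (SE 0.28, adjusted p = 0.000191). Acot3, a peroxisomal acyl-CoA thioesterase, fell by 2.89, and Pnpla5, a lipase of the patatin family, rose by 2.96 (SE 0.43, adjusted p = 0.00123). Slc25a30, a mitochondrial carrier, rose by 2.03 and Serpina7, thyroxine-binding globulin, by 1.79. Fgf21, a fasting-induced liver hormone, stood at 86.9 ± 34.2 at 0 ppm and 27.8 ± 23.2 at 0.1 ppm. Its change against the mean of the supplemented diets was 2.12 (adjusted p = 0.0191), a call lost without 0 ppm a (0.0573) or b (0.0939). In all, 1252 of 18945 genes differed between 0 ppm and the supplemented diets, 416 higher and 836 lower (66.8%), and 3833 had an unadjusted p under 0.05. The split was 544 to 661 (54.9% lower) under quantile normalization and 645 to 727 (53% lower) with edgeR on the recovered reads. Without library 0 ppm a the count was 535, without the mean-variance trend 488 and with 2 clock components as covariates 0. Among the genes named for this comparison, Txnrd2, Selenoo, Selenoi, Sephs2, Fgf21, Sdhd, Fmo2, Dnaja1, Gclc, Fga, Fgg and Hamp lost their calls without the trend (adjusted p = 0.0525 to 0.121), Fmo2 with robust moderation (0.0626) and Selenoo under quantile normalization (0.0654).

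Of 35 measured interferon-response genes, which act in antiviral defence, 15 rose and none fell at 0 ppm in liver, and 24 were higher when adjusted over the list alone (camera adjusted p = 1.55e-15; adjusted p = 0.305 with an estimated correlation). Ifi47, an interferon-inducible GTPase, rose by 1.19 (SE 0.18, adjusted p = 0.00151), Isg15, a ubiquitin-like protein, by 0.74 (SE 0.10, adjusted p = 0.000686) and Ddx58, the RNA sensor RIG-I, by 0.49 (SE 0.08, adjusted p = 0.00205). Of genes of the methionine cycle and one-carbon metabolism 12 of 27 fell and 2 rose (16 and 3 when adjusted over the list alone; camera adjusted p = 1.49e-05; adjusted p = 0.305 with an estimated correlation). Mat1a, the liver methionine adenosyltransferase, fell from 91702 ± 12759 normalized reads at 0.1 ppm to 45712 ± 7365 at 0 ppm, and its log2 change against the mean of the supplemented diets was -0.94 (SE 0.13, adjusted p = 0.000696). Ahcy, which splits S-adenosylhomocysteine, fell by 0.99 (SE 0.11, adjusted p = 0.000227).

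Of genes regulated by the xenobiotic receptors CAR and PXR, 6 of 21 fell and none rose at 0 ppm in liver (12 and 0 when adjusted over the list alone; camera adjusted p = 1.49e-05; adjusted p = 0.398 with an estimated correlation; camera adjusted p = 0.0643 without library 0 ppm c). Por, the electron donor of cytochromes P450, had a log2 change of -1.30 (SE 0.16, adjusted p = 0.000336), and Sult1d1, a sulfotransferase, of -1.25 (SE 0.11, adjusted p = 3.24e-05). Cyp2b10, the classic CAR target, fell by 1.78, with near-identical family members that make its value uncertain. In the gluconeogenesis and glycolysis list 6 of 17 genes fell and none rose (9 and 0 when adjusted over the list alone; camera adjusted p = 3.19e-05; adjusted p = 0.379 with an estimated correlation). These included Got1, a cytosolic transaminase, at -1.37 (SE 0.17, adjusted p = 0.000491). Hepatocyte markers fell as a list, with 2 of 11 lower and 1 higher (6 and 1 when adjusted over the list alone; camera adjusted p = 0.000465; adjusted p = 0.398 with an estimated correlation). The lower members were the urea cycle enzymes Cps1, at -0.89 (adjusted p = 0.000457), and Ass1, at -0.86 (adjusted p = 0.000502). Endothelial markers were lower as a list, with 2 of 11 lower, among them Flt1, a VEGF receptor, at -0.64 (7 when adjusted over the list alone; camera adjusted p = 2.13e-05; adjusted p = 0.305 with an estimated correlation).

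Circadian clock genes differed among the diets in liver. At 0 ppm, 9 of 19 were lower and 1 higher than at the supplemented diets (11 and 2 when adjusted over the list alone; camera adjusted p = 0.000511; adjusted p = 0.142 with an estimated correlation). Cry1 and Cry2, repressors in the clock loop, fell by 2.02 (SE 0.25, adjusted p = 0.000362) and by 0.72 (SE 0.08, adjusted p = 0.000216), and Nr1d1, a repressor of Arntl, rose by 1.96 (SE 0.22, adjusted p = 0.000246). Library 0 ppm c stood apart from a and b in some clock genes, picked after their values were seen: Dbp was 428, 463 and 1672, Ciart 33.3, 58.8 and 259, and Arntl 136, 185 and 35.7 normalized reads in 0 ppm a, b and c. Without 0 ppm c, 8 clock genes were lower and 2 higher. Diet explained 66.3% and 94.1% of the variance of the first and second principal components of these genes over the 12 liver libraries. The labels give no time of collection or feeding.

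**Figure D2:**
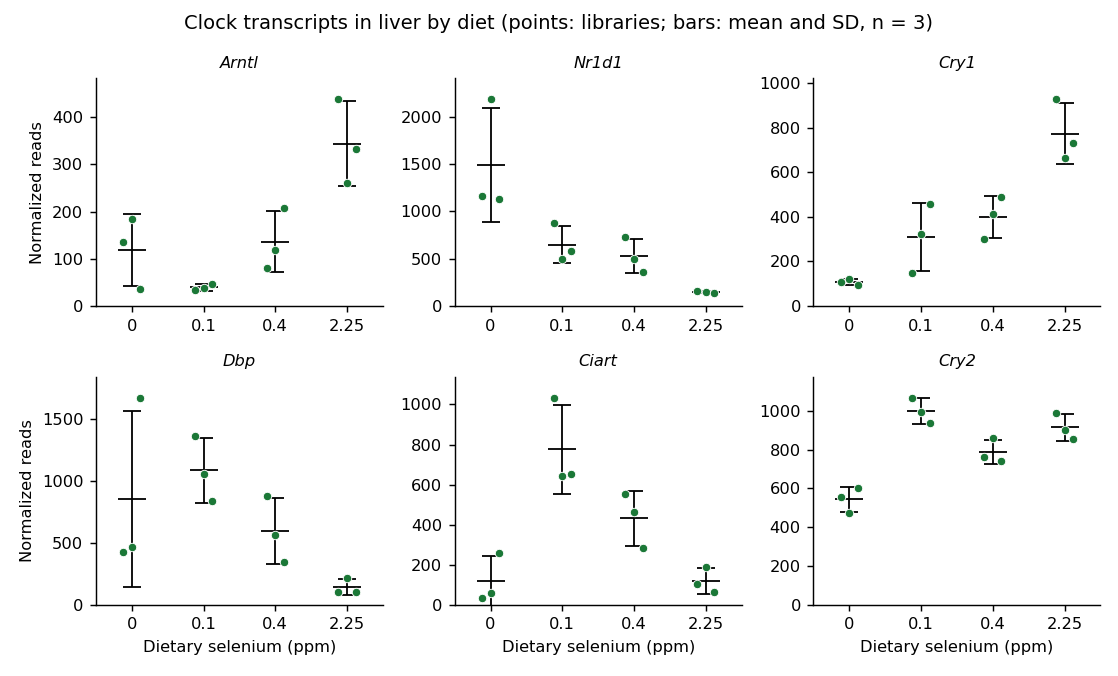
Normalized reads of 6 clock genes in each liver library (points) against dietary selenium (ppm), with the mean and SD of 3 libraries per diet. Arntl averages 39.8 at 0.1 ppm and 344 at 2.25 ppm, and Cry1 averages 108 at 0 ppm and 773 at 2.25 ppm.

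Oxidative phosphorylation genes were lower by a median log2 of -0.14 at 0 ppm in liver, with all 40 below 0 but only Sdhd called (0 when adjusted over the list alone; camera adjusted p = 9.16e-08; adjusted p = 0.742 with an estimated correlation). Sdhd, a subunit of succinate dehydrogenase, was lost under quantile normalization (adjusted p = 0.0774) and without 0 ppm a or c, 0.1 ppm b or c, 0.4 ppm a or b, or 2.25 ppm a or b (0.0553 to 0.149). Of 13 female-biased liver genes 5 fell (8 when adjusted over the list alone; camera adjusted p = 1.49e-05; adjusted p = 0.286 with an estimated correlation), including Fmo2 at -1.32 (adjusted p = 0.0107), which was lost without 0 ppm a (0.0876). PPAR alpha targets, genes of fatty acid oxidation, had 7 of 32 lower and 2 higher (11 and 3 when adjusted over the list alone; camera adjusted p = 0.00192; adjusted p = 0.808 with an estimated correlation; camera adjusted p = 0.65 without 0 ppm c). Acot3, at -2.89, was among the lower members, while Plin2, which coats lipid droplets, rose by 1.16 (SE 0.17, adjusted p = 0.000992). Cholesterol synthesis had 5 of 25 higher and none lower, Nsdhl among them at 0.46 (8 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.00287, and 0.209 without 0 ppm c). NRF2 targets, genes of the antioxidant response, had 7 of 40 higher and 2 lower (11 and 2 when adjusted over the list alone; camera adjusted p = 0.0157, and 0.43, 0.358 and 0.0642 without 0 ppm a, 0 ppm b and 0.1 ppm a). Gclc, a subunit of the enzyme that starts glutathione synthesis, rose by 0.66 (adjusted p = 0.0164, and 0.116 and 0.0881 without 0 ppm a and b), and Cbr1, a carbonyl reductase, fell by 0.89 (adjusted p = 0.00157). Acute phase genes had 3 of 25 higher and 2 lower (4 and 2 when adjusted over the list alone; camera adjusted p = 0.00918, and 0.424 and 0.373 without 0 ppm a and c). The fibrinogen chains Fga and Fgg rose by 0.82 and 0.81 (adjusted p = 0.0132 and 0.0119, and 0.09 and 0.0854 without 0 ppm a), and Hamp, the iron hormone hepcidin, fell by 1.47. Heat shock genes had 1 of 15 lower, Dnaja1 at -0.57 (3 when adjusted over the list alone; camera adjusted p = 0.00937, and 0.373 without 0 ppm c), and the unfolded protein response had 2 of 21 higher (4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.0345). The last was lost without 0 ppm a or b, 0.1 ppm a or b, 0.4 ppm a, or 2.25 ppm a or b, with camera adjusted p from 0.0607 to 0.501, and without the mean-variance trend (0.0763). For cholesterol synthesis, NRF2 targets, acute phase, heat shock and unfolded protein response, adjusted p = 0.808 with an estimated correlation. The remaining 34 of 50 lists had camera adjusted p from 0.0693 to 0.996, and the deposited NRF2 lists 1, 2 and 3, which the study supplied, had 0.754, 0.0693 and 0.626.

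**Figure D3:**
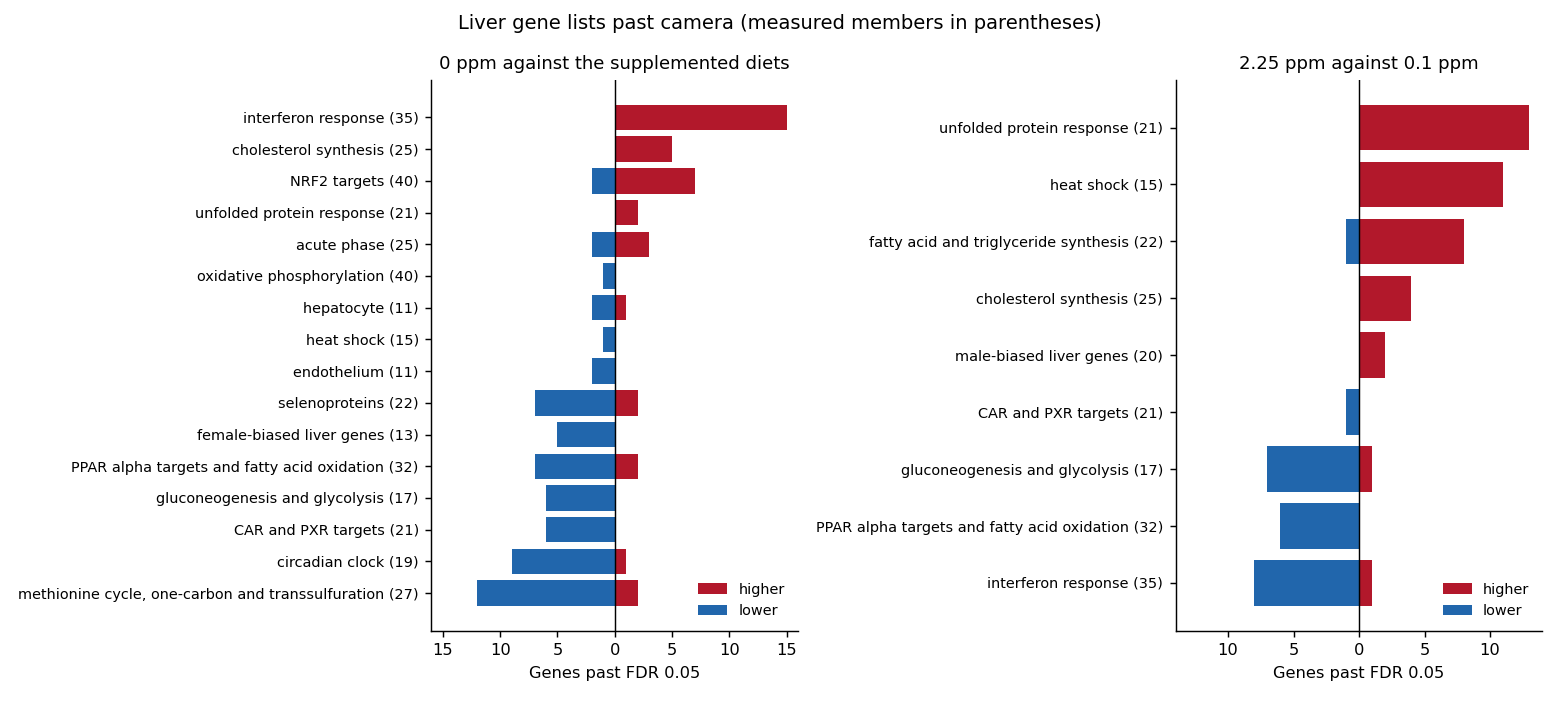
Number of genes past an FDR of 0.05 in each liver gene list that passed camera, higher to the right of 0 and lower to the left, for 0 ppm against the supplemented diets and for 2.25 against 0.1 ppm, with the measured members of each list in parentheses. The interferon response has 15 higher genes at 0 ppm and 8 lower and 1 higher at 2.25 ppm, and heat shock 1 lower at 0 ppm and 11 higher at 2.25 ppm.

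Set against 0.1 ppm alone, the 0 ppm diet again had lower Gpx1 and Selenow in liver. The changes were -1.36 (SE 0.09, adjusted p = 3.47e-06) for Gpx1, -1.64 (SE 0.08, adjusted p = 2.91e-07) for Selenow and -1.23 (SE 0.17, adjusted p = 0.000801) for Selenoh. Selenop fell by 0.56 (SE 0.13, adjusted p = 0.0216), a call lost without 0 ppm a or 0.1 ppm b or c (adjusted p = 0.0569 to 0.0993) and with only the 6 libraries (0.147). Of the 22 selenoproteins 7 were lower and 1 higher, and the same numbers held when adjusted over the list alone. In total 1161 genes differed, 345 higher and 816 lower (70.3%), and the split was 446 to 633 (58.7% lower) under quantile normalization. The count was 556 without 0 ppm a, 527 without 0.1 ppm b, 611 without 0.1 ppm c, 216 with only the 6 libraries, 404 without the mean-variance trend and 1 with 2 clock components as covariates.

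Between 0.4 and 0.1 ppm, both above the deficient diet, 282 liver genes differed, 104 higher and 178 lower at 0.4 ppm. Feeding and time of collection are not labelled here either, so neither can be told apart from the dose. The genes named here were chosen after their values were seen. Mfsd2a, a lysophospholipid transporter, fell from 3101 ± 246 normalized reads at 0.1 ppm to 923 ± 80.9 at 0.4 ppm (log2 change -1.75, SE 0.14, adjusted p = 0.000116). Ppargc1a, a coactivator of gluconeogenesis, fell from 565 ± 87.2 to 136 ± 18.1 (-2.04, SE 0.19, adjusted p = 0.000272), and Foxo1, a fasting-active transcription factor, fell by 0.73 (SE 0.11, adjusted p = 0.00608). Slc7a2, a cationic amino acid transporter, fell by 1.29 (SE 0.14, adjusted p = 0.000852). Mid1ip1, an activator of acetyl-CoA carboxylase, rose from 304 ± 11.6 to 1143 ± 239 (1.89, SE 0.18, adjusted p = 0.000359), and Angptl8, a feeding-induced secreted protein, from 233 ± 123 to 2200 ± 128 (3.36, SE 0.49, adjusted p = 0.00608). Tfrc, the transferrin receptor, rose by 0.95 (SE 0.14, adjusted p = 0.00523). No selenoprotein passed by limma over all genes, and 1, Selenoo at -0.37, was lower when adjusted over the list alone. Over all genes, 2986 had an unadjusted p under 0.05. The count of 282 fell to 84, 47, 132, 44 and 71 without 0.1 ppm a, 0.1 ppm b, 0.4 ppm a, 0.4 ppm b and 0.4 ppm c, reached 504 without 0 ppm c, and was 41 without the mean-variance trend, which ended the calls of Angptl8, Foxo1 and Tfrc (adjusted p = 0.0681 to 0.0776), and 24 with 2 clock components as covariates.

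Next, the diet of 2.25 ppm, the highest supplied, was compared with 0.1 ppm in liver. As the labels give no time of collection or feeding, a difference in either cannot be told apart from the selenium dose. Fasn, the fatty acid synthase, rose from 4885 ± 652 to 27778 ± 6627 normalized reads, and Srebf1, the main lipogenic transcription factor, from 3518 ± 548 to 10455 ± 1687. Pck1, a key gluconeogenic enzyme, fell from 79378 ± 2461 to 23343 ± 8826, and Gpcpd1, a glycerophosphodiester phosphodiesterase, from 12484 ± 1160 to 1628 ± 781. Of the unfolded protein response list 13 of 21 genes rose, and of heat shock genes 11 of 15. Of the 7 selenoproteins that fell at 0 ppm only Selenoo passed, again lower, while Gpx1 was 28382 ± 236 at 2.25 ppm against 26972 ± 1263.

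The liver log2 changes at 2.25 ppm were 2.49 for Fasn (SE 0.17, adjusted p = 6.55e-06), 1.57 for Srebf1 (SE 0.22, adjusted p = 0.000998), 0.89 for Mlxipl, the glucose-sensing factor ChREBP (SE 0.11, adjusted p = 0.000511), and 2.73 for Mid1ip1 (SE 0.18, adjusted p = 6.48e-06). Lpin1, a phosphatidate phosphatase, fell by 1.87 (SE 0.21, adjusted p = 0.000296). Some of these genes also had 0 ppm means away from 0.1 ppm on the same side as 2.25 ppm: at 0, 0.1, 0.4 and 2.25 ppm Mlxipl averaged 7644, 4339, 5302 and 8081 normalized reads, Lpin1 4263, 13681, 8342 and 3765, Pck1 42807, 79378, 27334 and 23343, and Gpcpd1 3242, 12484, 4920 and 1628. In the fatty acid and triglyceride synthesis list 8 of 22 rose and 1 fell, with a median log2 change of 0.08 (10 and 2 when adjusted over the list alone; camera adjusted p = 0.0285, and 0.172, 0.0822, 0.0783 and 0.0769 without 0.1 ppm a, 0.1 ppm c, 2.25 ppm b and the mean-variance trend). Of the gluconeogenesis and glycolysis list 7 of 17 fell and 1 rose (9 and 1 when adjusted over the list alone; camera adjusted p = 0.000464), with Pck1 at -1.83 (SE 0.28, adjusted p = 0.0018), Ppargc1a at -1.90 (SE 0.19, adjusted p = 0.000123) and Foxo1 at -0.98 (SE 0.11, adjusted p = 0.000212). PPAR alpha targets had 6 of 32 lower and none higher (9 and 0 when adjusted over the list alone; camera adjusted p = 3.99e-06), with Cpt1a, which admits fatty acids to mitochondria, at -0.84 (SE 0.13, adjusted p = 0.00147). Cholesterol synthesis had 4 of 25 higher, such as Fdps at 1.12 (4 when adjusted over the list alone; camera adjusted p = 0.000209, and 0.0926 without 2.25 ppm b). The call of Fdps was lost without the mean-variance trend (adjusted p = 0.0537). For each of the 9 lists that passed in this contrast, adjusted p = 0.937 with an estimated correlation.

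Unfolded protein response genes rose at 2.25 ppm in liver, 13 of 21 and none falling (17 when adjusted over the list alone; camera adjusted p = 1.63e-13; adjusted p = 0.937 with an estimated correlation). Syvn1, a ubiquitin ligase of the endoplasmic reticulum, rose by 1.71 (SE 0.27, adjusted p = 0.0022), Manf, a stress-induced secreted protein, by 1.51 and Calr, the chaperone calreticulin, by 0.73. Heat shock genes rose in 11 of 15 and fell in none (12 when adjusted over the list alone; camera adjusted p = 1.39e-10; adjusted p = 0.937 with an estimated correlation). Hspb1 rose by 1.84 (SE 0.32, adjusted p = 0.00349), Hspa8, the constitutive 70 kDa chaperone, by 1.39 (SE 0.25, adjusted p = 0.00455) and Dnajb1 by 1.45. With only the 6 libraries the calls of Hspb1 and Hspa8 were lost (adjusted p = 0.052 and 0.0536). Interferon-response genes fell in 8 of 35 and rose in 1 (12 and 1 when adjusted over the list alone; camera adjusted p = 6.30e-06; adjusted p = 0.937 with an estimated correlation), with Usp18, a negative regulator of the pathway, at -1.59 (SE 0.19, adjusted p = 0.000372) and Isg15 at -0.57. CAR and PXR targets had Cyp2a5 lower, at -0.76, among 21 (3 when adjusted over the list alone; camera adjusted p = 0.0119, and 0.137 without 0.1 ppm c), and male-biased liver genes had 2 of 20 higher (4 when adjusted over the list alone; camera adjusted p = 0.0179, and 0.121, 0.0512 and 0.107 without 0.1 ppm c, 2.25 ppm a and 2.25 ppm b). For these 2 lists too, adjusted p = 0.937 with an estimated correlation. The Cyp2a family and the members of the male-biased list, such as Serpina1e, have near-identical copies, so these values are uncertain. The remaining 41 of 50 lists had camera adjusted p from 0.105 to 0.973.

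Clock genes also stood apart at 2.25 ppm in liver, with 4 of 19 higher and 5 lower (7 and 5 when adjusted over the list alone; camera adjusted p = 0.868). Arntl, the activator BMAL1, rose by 3.06 (SE 0.47, adjusted p = 0.00181), and Dbp, a clock output factor, fell by 2.99 (SE 0.46, adjusted p = 0.00179). Of the 22 selenoproteins Selenoi rose by 0.49 (SE 0.09, adjusted p = 0.00387) and Selenoo fell by 0.54 (SE 0.10, adjusted p = 0.00459), and 1 each way also passed when adjusted over the list alone. Gpx1, Selenow and Selenop changed by 0.07 (adjusted p = 0.709), 0.07 (adjusted p = 0.718) and 0.10 (adjusted p = 0.724). In total 1487 genes differed, 801 higher and 686 lower. The count was 968 without 0.1 ppm a, 692 without 0.1 ppm b, 918 without 2.25 ppm a, 803 without 2.25 ppm c, 738 with only the 6 libraries, 751 without the mean-variance trend and 0 with 2 clock components as covariates. A test for any difference among the 4 diets called 2056 liver genes, 13 of the 19 clock genes among them (1217 without 0.1 ppm b, 583 without the mean-variance trend and 44 with 2 clock components as covariates).

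In brain, 4 genes passed between 0 ppm and the supplemented diets, all lower. Fmo2, a flavin monooxygenase, fell to 21.4 ± 1.02 normalized reads from 45.5 ± 3.75, 78.3 ± 2.63 and 63.7 ± 4.98 at 0.1, 0.4 and 2.25 ppm (log2 change -1.47, SE 0.11, adjusted p = 5.67e-05), and its call held without any single library. Plin4, a lipid droplet protein, fell by 2.03 (SE 0.26, adjusted p = 0.0262), Mfsd2a, which carries docosahexaenoic acid across the blood-brain barrier, by 0.67 (SE 0.10, adjusted p = 0.0388) and Kirrel2, an adhesion protein, by 0.98 (SE 0.14, adjusted p = 0.0388). Next by p was Fgfr3, a growth factor receptor, at -0.42 (adjusted p = 0.0559). Of 23 selenoproteins measured in brain none passed by limma, and Selenow was the single gene lower when adjusted over the list alone. Its change against the mean of the supplemented diets was -0.24 (SE 0.06, adjusted p = 0.476), with 2318 ± 121 at 0 ppm and 2762 ± 129 at 0.1 ppm. Txnrd1 and Selenov changed by -0.10 (adjusted p = 0.896) and -0.41 (adjusted p = 0.912), and Gpx1, Selenop and Gpx4 by -0.05, -0.03 and 0.06. With 21127 genes tested, 1173 had an unadjusted p under 0.05, edgeR called 1 gene and quantile normalization left 2. The count was 1 without 0 ppm a, 0 ppm b, 0.1 ppm b, 0.1 ppm c or 0.4 ppm b, 2 without 0.4 ppm c or 2.25 ppm c, and 10 without 0.1 ppm a. Plin4 was lost without 0 ppm a or b, 0.1 ppm b or c, or 0.4 ppm b (adjusted p = 0.0544 to 0.321). Mfsd2a (0.0594 to 0.334) and Kirrel2 (0.0594 to 0.321) were lost without those and without 0.4 ppm c or 2.25 ppm c, Kirrel2 also without 0 ppm c and 2.25 ppm b. These 3 calls were also lost with edgeR (0.0941), without the mean-variance trend (0.183) and without the 2 libraries described next (0.696).

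Hepatocyte transcripts were present at low and varying levels in the brain libraries, and pituitary transcripts were high in 2 of the 12. The level of 60 liver-specific genes was 75.5 to 93.4 millionths of that in liver in the 0 and 0.1 ppm libraries and 0.4 ppm a, and 30.5 to 44.1 in the other 5. Albumin (Alb) stood at 63.6 ± 7.11, 50.3 ± 6.69, 16.3 ± 27.0 and 4.01 ± 5.74 normalized reads at 0, 0.1, 0.4 and 2.25 ppm in brain. Growth hormone (Gh) stood at 73058 in library 0 ppm a and 45384 in library 0.1 ppm b, against at most 388 in the others. At 0 ppm, 14 of 52 lists passed camera in brain although only Fmo2, of the female-biased list, was called among their members over all genes. Higher were male-biased liver genes (3 when adjusted over the list alone), hepatocyte markers (5 higher and 1 lower), the unfolded protein response (2), acute phase, cytosolic ribosomal proteins, pituitary markers, heat shock, cholesterol synthesis, interferon response, oxidative phosphorylation and cerebellum markers (0 each). Lower were the circadian clock (6, with 2 higher), choroid plexus markers (0) and female-biased liver genes (1). Their camera adjusted p ran from 1.68e-05 for male-biased liver genes to 0.0494 for cerebellum markers, and the smallest was adjusted p = 0.319 with an estimated correlation. In the clock list Per3 and Bhlhe41 had changes of -0.39 (adjusted p = 0.0871) and -0.32 (adjusted p = 0.12).

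Single brain libraries carried part of these list calls. Without 0 ppm a, 7 lists passed, and the camera adjusted p was 0.416 for cholesterol synthesis, 0.681 for ribosomal proteins, 0.681 for pituitary markers, 0.0903 for heat shock, 0.0653 for interferon response, 0.0653 for female-biased liver genes, 0.101 for oxidative phosphorylation and 0.111 for the unfolded protein response. Without 0 ppm b it was 0.273 for cholesterol synthesis, 0.31 for heat shock, 0.761 for choroid plexus and 0.0659 for cerebellum markers. Without 0 ppm c it was 0.331 for interferon response, 0.807 for oxidative phosphorylation, 0.871 for cerebellum markers and 0.0803 for female-biased liver genes. Female-biased genes also lost their call without 0.1 ppm c (0.0513), oxidative phosphorylation without 0.1 ppm c (0.088), 0.4 ppm a (0.126) and 2.25 ppm b (0.15), and cerebellum markers without 0.1 ppm b (0.414), 0.4 ppm c (0.227), 2.25 ppm a (0.178) and 2.25 ppm b (0.14). With genes at least 100 times higher in liver left out, the male-biased, acute phase and cerebellum lists had camera adjusted p of 0.548, 0.572 and 0.0555. Without the 2 pituitary-rich libraries it was 0.215 for cholesterol synthesis, 0.109 for oxidative phosphorylation, 0.986 for ribosomal proteins and 0.512 for pituitary markers, and with the stricter filter 0.0502 for hepatocyte and for cerebellum markers. The remaining 38 lists had camera adjusted p from 0.061 to 0.972, the selenoproteins 0.972 and the deposited NRF2 lists 1, 2 and 3 0.968, 0.162 and 0.95.

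Between 0 and 0.1 ppm, 6 brain genes passed, named here after their values were seen. Slc2a1, the glucose transporter of the blood-brain barrier, fell from 2140 ± 283 to 1232 ± 96.8 normalized reads (log2 change -0.79, SE 0.10, adjusted p = 0.0184), Fmo2 fell by 1.05 (SE 0.13, adjusted p = 0.0184), and Hif3a and Plekhg2 fell by 1.22 and 0.76 (adjusted p = 0.0377 for both). Clec2d, a C-type lectin, rose by 1.21 and Uba6, a ubiquitin-activating enzyme, by 0.55 (adjusted p = 0.0377 for both). No gene passed without 0 ppm a or b, 0.1 ppm b or c, 0.4 ppm b or c, or 2.25 ppm b, 3 passed without 0.4 ppm a and 2 without 2.25 ppm a or c, and none passed with only the 6 libraries or without the 2 pituitary-rich libraries. Slc2a1 and Fmo2 were lost without the 7 libraries first named (adjusted p up to 0.133), and Clec2d, Hif3a, Uba6 and Plekhg2 in addition without most others, Hif3a holding without 0.1 ppm a and Uba6 without 0 ppm c (up to 0.259). The genes with an unadjusted p under 0.05 numbered 1468, edgeR called 4, and no selenoprotein passed, also when adjusted over the list alone. Between 0.4 and 0.1 ppm, Clec2d rose from 18 ± 3.37 to 55.4 ± 5.70 (1.58, SE 0.18, adjusted p = 0.0108) and Nes, the progenitor-cell filament nestin, fell by 1.34 (SE 0.17, adjusted p = 0.0229). No other gene passed, 1708 had an unadjusted p under 0.05 and edgeR called 3. The count was 0 without any of the 0.4 ppm libraries, 1 without 0 ppm a or 2.25 ppm b and 4 without 2.25 ppm a. Clec2d was lost without each 0.4 ppm library (adjusted p = 0.0515 to 0.107) and Nes without those and 0 ppm a, 0.1 ppm b, 0.1 ppm c or 2.25 ppm b (up to 0.224), and both were lost with only the 6 libraries (0.0732), Nes also without the mean-variance trend (0.105) and without the pituitary-rich libraries (0.103). The test for any diet difference called Fmo2, Clec2d, Slc2a1 and Nes (adjusted p = 0.000262, 0.0114, 0.0311 and 0.046), with 1999 genes at an unadjusted p under 0.05. That count was 1 without 0.1 ppm b or 0.4 ppm b, 2 without 0 ppm a or 0.4 ppm c, 10 without 0 ppm c and 13 without 0.1 ppm a.

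At 2.25 against 0.1 ppm, 92 brain genes passed, 48 higher and 44 lower. Clec2d rose from 18 ± 3.37 to 55.8 ± 5.24 normalized reads, Erbb3, a receptor of the oligodendrocyte lineage, from 148 ± 5.24 to 287 ± 69.2 and Cldn5, a tight-junction protein of brain endothelium, from 202 ± 48.1 to 369 ± 69.9. Nes fell from 281 ± 69.2 to 120 ± 10.7 and Txnip, a thioredoxin-binding protein that rises with glucose, from 408 ± 69.5 to 202 ± 2.83. The log2 changes were 1.59 for Clec2d (SE 0.18, adjusted p = 0.00983), 0.92 for Erbb3 (SE 0.14, adjusted p = 0.0261), 0.88 for Cldn5 (SE 0.16, adjusted p = 0.0316), -1.20 for Nes (SE 0.17, adjusted p = 0.0251) and -0.99 for Txnip (SE 0.19, adjusted p = 0.0459). Xbp1, a transcription factor of the unfolded protein response, rose by 0.58 (SE 0.10, adjusted p = 0.0273), and Maff, a small Maf protein, fell by 1.75 (SE 0.34, adjusted p = 0.0465). Txnip varied within diets along with the pituitary hormone transcript Gh. No selenoprotein passed by limma, and Txnrd1 alone was higher when adjusted over the list alone, at 0.27 (SE 0.06, adjusted p = 0.0704 over all genes). edgeR called 80 genes and 2757 had an unadjusted p under 0.05. All of these calls were lost without 0.1 ppm b or 2.25 ppm c, when the count was 0, and with only the 6 libraries, when it was 0 again. Among the genes named, Erbb3, Cldn5, Nes, Txnip, Xbp1, Maff, Creld2 and Chordc1 each lost the call without further libraries, all without 0.4 ppm b and 2.25 ppm a and some without 0 ppm b, 0.1 ppm a, 0.1 ppm c, 0.4 ppm a, 0.4 ppm c or 2.25 ppm b (adjusted p up to 0.149). All but Clec2d were lost without the mean-variance trend (0.0892 to 0.124), when 12 genes passed. The count was 149 without 0 ppm c, 9 without 0.1 ppm a, 36 without 0.1 ppm c, 55 without 0.4 ppm a, 6 without 0.4 ppm b, 48 without 0.4 ppm c, 2 without 2.25 ppm a, 21 without 2.25 ppm b and 3 without the 2 pituitary-rich libraries.

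Unfolded protein response genes were higher as a list at 2.25 ppm in brain too, with Xbp1 and Creld2 called among 21 (11 when adjusted over the list alone; camera adjusted p = 1.72e-10; adjusted p = 0.565 with an estimated correlation). Hspa5, the chaperone BiP, had a change of 0.65 (adjusted p = 0.059). Heat shock genes had Chordc1 called among 15 (6 when adjusted over the list alone; camera adjusted p = 5.19e-10; adjusted p = 0.565 with an estimated correlation). Endothelial markers had 1 of 11 higher, Cldn5 (4 when adjusted over the list alone; camera adjusted p = 0.0152, and 0.115 without 2.25 ppm a). Cholesterol synthesis was lower, with 1 of 25 called (2 when adjusted over the list alone; camera adjusted p = 0.000247). Striatum markers were higher as a list (0 called of 9, over all genes or when adjusted over the list alone; camera adjusted p = 0.00362, and 0.371 and 0.115 without 0.1 ppm a and 2.25 ppm b). Choroid plexus markers were lower (0 called of 11, 1 when adjusted over the list alone; camera adjusted p = 0.000183), and so were lists in which no member was called over all genes. These were acute phase (5 when adjusted over the list alone; 0.000515), CAR and PXR targets (7; 0.00277), hepatocyte markers (2; 0.0115, and 0.0713 without 0.1 ppm b) and male-biased liver genes (3; 0.0193, and 0.0617, 0.0687 and 0.0755 without 0.1 ppm a, 0.1 ppm b and 2.25 ppm c). Pituitary markers (0; 0.00127, and 0.123 without 0.1 ppm b) and muscle markers (0; 0.0193, and 0.833 and 0.0663 without 0.1 ppm c and 2.25 ppm a) were lower as well. The deposited NRF2 list 1, which the study supplied, passed upward with 0 of 129 called, also when adjusted over the list alone, at camera adjusted p = 0.0396, with a median of 0.05 but a mean of -0.02. It was lost without 0.1 ppm c (0.169), 2.25 ppm a (0.0696) and 2.25 ppm b (0.0666), and under quantile normalization (0.336). For these lists adjusted p = 0.565 to 0.659 with an estimated correlation. With genes at least 100 times higher in liver left out, camera adjusted p was 0.195 for acute phase, 0.115 for CAR and PXR targets and 0.778 for male-biased genes, and without the 2 pituitary-rich libraries 0.118 for male-biased genes and 0.0809 for hepatocyte markers. The remaining 39 of 52 lists had camera adjusted p from 0.068 to 0.979, the clock 0.979 with 1 member lower (3 lower and 1 higher when adjusted over the list alone), and the selenoproteins 0.919. Under quantile normalization 15 lists passed, 4 upward and 11 downward, against 5 and 8.

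**Figure D4:**
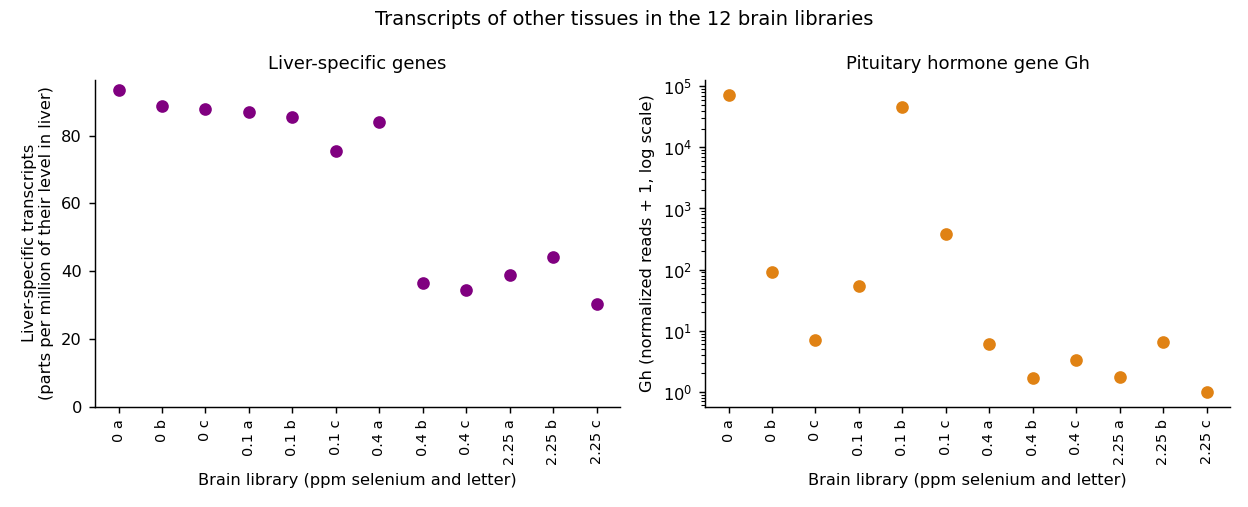
Transcripts of other tissues in each of the 12 brain libraries, a point per library ordered by dietary selenium (ppm): the mean level of 60 liver-specific genes in millionths of their liver level, and growth hormone (Gh) in normalized reads plus 1 on a log scale. Gh is 73058 in library 0 ppm a and 45384 in library 0.1 ppm b, and the liver-specific level averages 90.1, 82.7, 51.6 and 37.8 at 0, 0.1, 0.4 and 2.25 ppm.

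Whether the effect of the 0 ppm diet differed between liver and brain was tested as an interaction over genes measured in both. Gpx1 and Selenow fell more in liver than in brain, with log2 differences of -1.35 (SE 0.08, adjusted p = 1.37e-09) and -1.50 (SE 0.08, adjusted p = 6.34e-10). Selenoh and Selenop differed by -1.07 (SE 0.16, adjusted p = 0.000958) and -0.62 (SE 0.10, adjusted p = 0.00102). Gpx4 differed by 0.05 (SE 0.08, adjusted p = 0.859) and Txnrd1 by -0.06 (SE 0.08, adjusted p = 0.822). In all 459 of 18186 genes differed between tissues, 139 with a higher and 320 with a lower change in liver (69.7%), a split of 204 to 256 (55.7% lower) with edgeR. The count was 237 without brain 0 ppm a, 267 without brain 0 ppm b, 266 without liver 0 ppm a, 815 without liver 0 ppm c, 248 without the mean-variance trend and 210 without the 2 pituitary-rich brain libraries.

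The authors' deposited table also gave a p-value per gene for each of 6 diet pairs in each tissue. Under 0.05, the authors' deposited table listed 2868 liver genes for 0 against 2.25 ppm, 2553 for 0 against 0.1 ppm and 3293 for 0.1 against 2.25 ppm. For brain the authors' deposited table listed 1430, 1363 and 2398. Adjusted here over all genes, the p-values of the authors' deposited table left 0, 13 and 77 liver genes and 3, 0 and 5 brain genes under 0.05 for those pairs.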

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

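The tests of the tissue difference without the 2 pituitary-rich brain libraries and without liver-specific genes were chosen only after the result was seen. The response to 0 ppm selenium differed between liver and brain, by the interaction test in limma, for 459 genes, and for 36 of the 72 genes named for 0 ppm and measured in both tissues. Values below are the log2 change in liver minus that in brain. Among selenoproteins the difference was -1.35 for Gpx1, -1.50 for Selenow, -1.07 for Selenoh, -0.62 for Selenop, -0.30 for Msrb1 and 0.32 for Selenoi. Clock and cell-cycle genes differed by 1.90 for Nr1d1, -1.78 for Cry1, -0.52 for Cry2 and -1.66 for Wee1.

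Genes of liver metabolism differed by -1.83 for Mat1a, -0.90 for Ahcy, -0.51 for Sardh, -1.16 for Por, -1.75 for Sult1d1, -1.41 for Got1, -1.90 for Cps1, -0.80 for Ass1, -3.20 for Acot3, -1.74 for Acot1, -0.88 for Cbr1 and 0.68 for Gclc. Cholesterol synthesis genes differed by 0.48 for Nsdhl, 0.45 for Sc5d and 0.40 for Acat2. The remaining differences were 3.02 for Efna3, 2.02 for Slc25a30, 1.82 for Spon2, -2.64 for Slc16a5, -2.56 for Eif4ebp3, -0.64 for Dnaja1, -0.64 for Flt1, -0.33 for Sdhd and 1.52 for Plin4. In brain Spon2 averaged 2.19 and Sult1d1 0.59 normalized reads, where 3 reads correspond to 1.75 to 2.34, so a response there could hardly be measured. Efna3 averaged only 10.9 in liver, and its liver call at 0 ppm was lost without 0 ppm a (adjusted p = 0.0661 by limma). Serpina1e (-2.29) and Mup3 (-1.67) have near-identical copies. Of these genes 8 were at least 100 times higher in liver than in brain, and 5 of the 8 belong to the liver transcripts with higher values in brain libraries at 0 ppm, so that part of their difference came from brain. For 3 of them, Cps1, Serpina1e and Mup3, the change in brain was over 0.5 times the difference, and for the last 2 nearly all of it. Their changes in brain, none past the test there, were 0.90 for Mat1a, 1.01 for Cps1, 0.49 for Sult1d1, 2.14 for Serpina1e and 1.53 for Mup3, against -0.94, -0.89, -1.25, -0.15 and -0.14 in liver.

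Of 100 splits of the libraries within each tissue, the real one included, 1 gave as many genes with a tissue difference as the real 459, and the highest of the others gave 325. The splits relabelled the diets in both tissues, so they tested for no diet effect in either tissue, not for equal effects in both. Only in that sense can chance be excluded for the count over all 24 libraries at this number of splits. A diet effect in liver alone would also raise the real count above the splits. The count fell below 325 without brain 0 ppm a (237) and without the pituitary-rich libraries, and no splits were made for those fits. The count was 210 without the 2 pituitary-rich brain libraries and 428 without liver-specific genes, which made up 33 of the 459.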

How the results depend on the processing

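The tests with edgeR, with 2 clock components, without the 2 pituitary-rich brain libraries and without liver-specific genes were chosen only after the result was seen. No paired analysis was possible because the columns carry no replicate numbers, and the planned replicate block was not run. Of 148 gene calls, 142 kept their direction and call under quantile normalization, 142 with edgeR, 135 with robust moderation, 147 without a filter, 85 without the mean-variance trend and 148 with the stricter filter or a pseudocount of 0.1. With 2 clock components 6 kept them, 125 lost the call and 17 reversed. When single libraries were left out 87 held in each fit, with only the 6 libraries 46 of 80, and without the pituitary-rich libraries 4 of 27 in brain. Of 52 list calls none held with an estimated correlation, and 24 held without each library. In liver 3 reads correspond to up to 5.32 normalized reads, which limits genes near that level. Unless stated, the cause was not tested.

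Liver counts are given for 0 ppm against the supplemented diets, 0 against 0.1, 0.4 against 0.1, 2.25 against 0.1 ppm and any diet. They were 488, 404, 41, 751 and 583 without the mean-variance trend and 1997, 1761, 632, 2297 and 3249 at a threshold of 0.1, which admits more genes. With 2 clock components they were 0, 1, 24, 0 and 44, while limma without them had 3833 genes at an unadjusted p under 0.05 for the first. Diet explained 66.3% of the first component and 94.1% of the second, and the median SE was 3.96 times larger with both. With only the 6 libraries, fewer samples, they were 216 for 0 against 0.1 ppm and 738 for 2.25 against 0.1 ppm. Leaving out single libraries gave 535 to 1509, 527 to 1450, 44 to 504, 692 to 1820 and 1217 to 2504. Liver lists past camera numbered 0 and 0 with an estimated correlation, and 13 to 18 at 0 ppm and 6 to 11 at 2.25 ppm without single libraries.

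Brain counts in the same order were 1, 1, 4, 12 and 4 without the trend, 14, 10, 3, 273 and 48 at a threshold of 0.1, and 1, 1, 0, 1 and 0 with 2 clock components. Quantile normalization gave 2 and edgeR 1 for 0 ppm, and robust moderation 8 for 0 ppm and 30 for any diet. With only the 6 libraries, 0 genes passed for 0 against 0.1 and for 2.25 against 0.1 ppm. Without the pituitary-rich libraries the counts were 1 for 0 ppm, 0 for 0 against 0.1 ppm, 3 for 2.25 against 0.1 ppm and 1 for any diet. Leaving out single libraries gave 1 to 10, 0 to 6, 0 to 4, 0 to 149 and 1 to 13. Brain lists numbered 0 and 0 with an estimated correlation, and 7 to 16 and 11 to 15 without single libraries. The tissue difference gave 248 without the trend, 762 at a threshold of 0.1, 210 without the pituitary-rich libraries and 237 to 815 without single libraries.

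In liver diet explained 66.3% and 94.1% of the 2 clock components, and the median SE for the 0 ppm contrast was 3.96 times larger with both. Lost calls and turned signs in that fit therefore cannot tell the clock from diet. With 2 clock components these log2 changes reversed. In liver at 0 ppm they were -2.73 for Efna3, -0.52 for Nr1d1, 0.51 for Eif4ebp3, -0.038 for Isg15, -0.045 for Ddx58, 0.10 for Ahcy, 0.012 for Sardh, -0.45 for Gclc, -0.34 for Pgd, -0.049 for Pdia6 and 0.69 for Fmo2. In liver at 2.25 ppm they were -0.11 for Gpx1, -0.16 for Selenop, -0.10 for Gpx4, -0.051 for Txnrd1, -1.70 for Hspa1b, 0.74 for Rgs16, -0.062 for Hspb1, -0.48 for Hspa8, -0.47 for Dnajb1 and -0.35 for Hsp90aa1. In brain they were -0.040 for Gpx4 and 0.23 for Per2 at 0 ppm, and -0.019 for Selenow and -0.32 for Drd2 at 2.25 ppm. Quantile normalization gave 0.00085 for Selenop in brain at 0 ppm, -0.0013 for Gpx1 in brain, 2.25 ppm vs 0.1 ppm, and -0.039 for Gpx4 there. The male-biased list in brain at 2.25 ppm turned upward without liver-specific genes (camera adjusted p = 0.778). Leaving out single libraries reversed the following. Gpx4 in liver at 2.25 ppm ranged from -0.010 (without 2.25 ppm c) to 0.064. In brain at 0 ppm Gpx1 ranged from -0.093 to 0.0033 (without 0 ppm b), Selenop from -0.085 to 0.027 (without 0 ppm b), and Prl from -0.52 (without 0 ppm a) to 6.00. Pomc in brain, 0 ppm vs mean of the 0.1, 0.4 and 2.25 ppm diets, ranged from -0.34 (without 0 ppm a) to 3.21. In brain at 2.25 ppm Gpx1 ranged from -0.0057 (without 2.25 ppm a, below 0 also without 0.1 ppm c) to 0.066 and Gpx4 from -0.017 (without 2.25 ppm c, below 0 also without 0.1 ppm c or 2.25 ppm a) to 0.054. At 0 ppm in brain the camera adjusted p ranged from 7.75e-09 to 0.681 for ribosomal proteins and from 8.85e-07 to 0.681 for pituitary markers, both turning downward without 0 ppm a, and from 0.000355 to 0.871 for cerebellum markers, turning downward without 0 ppm c.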

Other observations

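The tests of the clock genes, of the pituitary markers, of the share of genes following Gh that was called and of the liver-specific genes were chosen only after the result was seen, whereas the splits of the samples and the correlation with Gh were planned. Over all 4 diets, several liver genes had their highest mean at 0.1 ppm. For Mfsd2a the means were 717 ± 93.7, 3101 ± 246, 923 ± 80.9 and 605 ± 143 normalized reads at 0, 0.1, 0.4 and 2.25 ppm (SD, n = 3). Ciart, a clock repressor, had liver means of 117 ± 124, 776 ± 223, 432 ± 137 and 119 ± 64.1 at the same diets, and Ppargc1a, Pck1, Lpin1, Gpcpd1 and Foxo1 also had their highest mean at 0.1 ppm. These genes were singled out after their values were seen.

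Clock genes of the liver differed among the diets. Library scaling is argued against, since 9 of the 9 clock genes called for 2.25 against 0.1 ppm kept their call and sign under quantile normalization and with edgeR. A time of day of collection that differed among diets may account for the pattern: 13 of 19 clock genes had the same sign in brain and liver for 2.25 minus 0.1 ppm and 10 of 19 for 0 ppm against the supplemented diets, and the median size of the change at 2.25 ppm was 0.19 in brain and 0.84 in liver. These values leave it open, and an effect of diet on the liver clock cannot be told apart from it because the labels give no time of collection. Whether such a time difference could also underlie the lower selenoprotein transcripts stays open for the set. Of the 7 lower selenoproteins, 5 changed by less than 0.5 times their 0 ppm change at 2.25 ppm: Gpx1, Selenow, Selenoh, Selenop and Msrb1, but not Selenoo and Txnrd2. At 0.1, 0.4 and 2.25 ppm Gpx1 averaged 26972, 27693 and 28382 normalized reads and Arntl 39.8, 136 and 344. For these 5, whatever moved the clock genes between 0.1 and 2.25 ppm did not move them alike, but the collection time at 0 ppm is unknown. With 2 clock components as covariates, Gpx1 had a log2 change of -1.26 (SE 0.30, against 0.07 without) and Selenow of -1.54 (SE 0.27, against 0.07).

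Pituitary transcripts were high in brain libraries 0 ppm a and 0.1 ppm b. Pituitary tissue kept with the brain may be the source but stays open, because the markers measured are those that singled out the libraries: 7 of the 8 markers were at least 4 times the highest other brain library in both, with Gh at 73058 and 45384 against 388, Prl at 8422 and 5205 against 69.2, and Pomc at 6600 and 1684 against 83.2. As the source of the brain calls for 2.25 against 0.1 ppm as a whole it stays open. Deviations from the diet mean correlated with those of Gh beyond 0.9 in size for 2.2% of the 92 calls. Such genes could be called, 2 of 124 (1.61%) against 0.435% of all 21127 tested, the 2 being Txnip and Fzd4. These values argue only against calls that mostly follow Gh so closely. They cannot speak for genes with a smaller pituitary share, and a gene that follows Gh spreads widely within the 0.1 ppm diet, which hinders a call. The count was 3 without both libraries, 0 without 0.1 ppm b and 69 without 0 ppm a, but also 0, 2 and 6 without 2.25 ppm c, 2.25 ppm a and 0.4 ppm b, where Gh was at most 0.723. An effect of diet on the pituitary was not tested.

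Hepatocyte transcripts were higher in brain libraries at 0 ppm than at 2.25 ppm. Liver RNA or reads carried into brain libraries may be the source but stay open. The higher mean was at 0 ppm for 95% of 60 genes at least 1000 times higher in liver (57 genes), which restates the pattern and would also follow from a diet effect, and across these genes, which are not independent replicates, the difference followed the liver level with Spearman's rho of 0.80. The level varied 2.45-fold among the 3 libraries of the 0.4 ppm diet, at 84.0, 36.5 and 34.3 millionths of the liver level. Alb was 47.5, 0 and 1.56 normalized reads in the same libraries, a, b and c. Alb, Serpina1e and Mup3 were each 0 in libraries 0.4 ppm b and 2.25 ppm c, where the level was 36.5 and 30.5. The level there came from others of the 60 genes, so it varied less than Alb. Diet alone does not account for the step within the 0.4 ppm diet. As that step rests on library 0.4 ppm a, a diet effect on hepatocyte genes expressed in brain cannot be told apart from carried-over RNA. The libraries lay at 75.5 to 93.4 millionths at 0 and 0.1 ppm and at 30.5 to 44.1 at 2.25 ppm. The brain comparison of 2.25 with 0.1 ppm thus falls across the same step. The most abundant of the 60 genes, Alb, averaged 63.6 normalized reads at 0 ppm.

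Other splits of the libraries were counted for each comparison, with the real split included. For liver, 1 of 100 splits gave as many genes as the real 1252 for 0 ppm against the supplemented diets (highest other 624), and 1 of 100 as many as the 2056 for any diet (highest other 474), so chance can be excluded for both counts over all 12 libraries. Without 0 ppm a the first count was 535, below 624, and no splits were made for that fit. For the 16 liver lists at 0 ppm, 6 of 100 splits gave as many (highest other 19), and chance cannot be excluded. For brain at 0 ppm, 6 of 100 splits gave at least 4 genes (highest other 298), and 5 of 100 gave at least 14 lists (highest other 16), so chance cannot be excluded for either. For any diet in brain, 4 of 100 gave at least 4 genes (highest other 54), and as another split far exceeded the real count, chance is not taken as excluded. What gave the high counts of 298 and 54 was not tested.

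The comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. In liver the real counts and highest others were 1161 and 25 for 0 against 0.1 ppm (1 split as large), 282 and 0 for 0.4 against 0.1 ppm (1), and 1487 and 0 for 2.25 against 0.1 ppm (1), by limma, with 9 and 13 lists for the last (6). In brain they were 6 and 104 (2), 2 and 0 (1), and 92 and 149 (2), with 13 and 17 lists for the last (3).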
